A study of Mus musculus with 9 samples.

How the data were processed

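RNA was sequenced from 9 libraries labelled as cells of the mouse line 4T1, in 3 groups of 3. The labels do not say whether the cells were cultured or taken from tumours. Per the labels' protocols, total RNA was extracted with Trizol, depleted of ribosomal RNA and made into libraries with a TruSeq Stranded Total RNA kit. Groups were taken from the sample titles. The treatment label of PD-1 replicates 2 and 3 carries the numbers 2 and 3 in the name of the treatment itself, and these libraries were grouped with PD-1 by title.

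The values the authors deposited are taken to be FPKM, a unit inferred from the values, since the file does not name it. The submitters' processing notes name CASAVA 1.8, Bowtie2, DESeq2 and the build mm9, with no role or order. The counting tool, the annotation and the use of strand are not given in the sources used here. The table held 52550 rows of versioned Ensembl gene identifiers, of which 99.7% were found in GENCODE M21 (an annotation of GRCm38), so the identifiers are later than mm9. Names and positions here come from that annotation on GRCm38. Symbols were found for 52403 rows, and 25103 rows were at 0 in every library. The sums of FPKM per library ran from 348764 to 370214.

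The depth was read from the low values. In genes with a single transcript of 300 nt or longer, FPKM times length fell on multiples of a step that differs between libraries, which points to between 8240000 and 8700000 fragments, a ratio of 1.056. Only between 25.4% and 28.4% of such values lay within 0.02 of a whole step, and between 39.6% and 41.7% within 0.02 of a whole or half-step multiple, so whole reads were not recovered. The planned count tests, edgeR's quasi-likelihood test and its DESeq2 alternative, need counts and were not run.

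The test that had been set for normalized values was used in their place. Genes at 1 FPKM or more in at least 3 libraries were kept (13990), log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with the 3 groups and no covariate, and empirical Bayes moderation used the trend and robust options. All 9 libraries entered the fit, so that the groups shared an estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The median standard error of a log2 fold change was 0.17. Tested on simulated data with 13990 genes, of which 100 were changed at each size, the fit recovered 57% of log2 changes of 1 and 89% of log2 changes of 2 in PD-1 against control, 59% and 83% in LY500307+PD-1 against control, and 58% and 89% in LY500307+PD-1 against PD-1. The simulated genes varied independently, which genes of these libraries do not.

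The comparisons, the tests, the 28 gene lists, the rule for named genes and the alternatives were set before the data were examined. The lists cover estrogen receptors and targets, myeloid growth factors, neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, dendritic cells, fibroblasts, endothelium, mammary epithelium, mesenchymal transition, interferon response, antigen presentation, immune checkpoints, cell cycle, hypoxia and glycolysis, p53 targets, unfolded protein and amino acid stress, cholesterol biosynthesis, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, histones, skeletal muscle, adipocytes, erythroid cells, immediate early genes and NF-kB targets. Lists with 5 or more tested members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The rule named, where no gene passes, the 5 genes with the smallest unadjusted p in each direction among genes with a mean of 1 FPKM or more whose groups do not overlap, leaving out by their symbols unnamed models and small RNAs that begin with Mir or Snor, for example. Rnu73b, a small nucleolar RNA, has another kind of symbol and stayed in. It also named up to 2 members of each list with the smallest p (here 2 for lists that passed camera and 1 for others), and Csf1, Csf1r, Esr1, Esr2, Cd274 and Pdcd1 throughout. The choice between 1 and 2 was made after the values were seen.

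The alternatives were quantile normalization, no filter on low values, a pseudocount of 0.1, only the 6 libraries compared, a fold minimum of 2, the replicate number as a block, and leaving out each library in turn. Unchanged groups against the shared controls were simulated 100 times from random combinations of the residuals. Tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and sequence comparisons BLAST 2.17.0. Permutation tests over libraries were exact and two-sided, except that of the variance between groups, which counted larger values alone.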

Results

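Gene expression was measured by RNA sequencing in 9 libraries labelled as 4T1, a mouse mammary carcinoma cell line. The libraries form 3 groups of 3, namely control, PD-1 treatment and LY500307 with PD-1 treatment. The labels call them cells and do not say whether these were cultured or taken from tumours. Markers of other cell types were present in each library, for example 193 to 736 FPKM of the macrophage marker Lyz2, 7.28 to 34.7 of the hemoglobin gene Hba-a2 and 7.43 to 13.7 of the endothelial marker Pecam1. These 3 were picked as examples after their values were seen, and values of such markers cannot be read as levels in 4T1 cells. LY500307 is an agonist of estrogen receptor beta, and PD-1 is an immune checkpoint receptor on T cells that checkpoint-blocking antibodies target. The deposited values are taken to be FPKM (fragments per kilobase of transcript, scaled to the size of the library), a unit inferred from the values, and the low values point to a depth of between 8240000 and 8700000 fragments per library. Between 20701 and 21480 genes had a value above 0 in a library. Pearson's r of log2(FPKM + 1) between pairs of libraries, taken across genes, had a median of 0.961 within groups and 0.967 between groups. The grouping accounted for 21.2% of the variance of the 13990 genes tested, against a mean of 25.0% over the 280 possible groupings into 3 groups of 3 (exact permutation p = 0.9). Values below are mean ± SD of 3 libraries, fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and gene positions are those of GENCODE M21 on GRCm38. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical in part.

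The receptor and ligand genes named in advance were present at widely differing levels. Esr2, which encodes estrogen receptor beta (ENSMUSG00000021055.14, chromosome 12, 76120419 to 76177259), was listed at 0 in 7 of the 9 libraries and at 0.0354 FPKM in control 2 and 0.0685 FPKM in PD-1 2. Esr1, which encodes estrogen receptor alpha (chromosome 10, 4611593 to 5005614), stood at 1.20, 0.819 and 0.635 FPKM in the control libraries, 0.969, 0.586 and 0.677 FPKM in the PD-1 libraries and 0.652, 0.876 and 0.803 FPKM in the LY500307+PD-1 libraries. Both genes missed the filter of 1 FPKM in 3 libraries and were not tested. Csf1, the macrophage colony-stimulating factor (chromosome 3, 107741048 to 107760469), averaged 25.4 ± 9.93 FPKM in control, 25.4 ± 4.64 in PD-1 and 23.4 ± 9.08 in LY500307+PD-1. Its receptor gene Csf1r (chromosome 18, 61100598 to 61132149) averaged 38.8 ± 23.1, 28.4 ± 5.75 and 27 ± 3.42 FPKM in the same order. Cd274, which encodes the PD-1 ligand PD-L1 (chromosome 19, 29367455 to 29388095), averaged 17.4 ± 4.74, 18.1 ± 3.72 and 21.3 ± 10.1 FPKM. Pdcd1, which encodes PD-1 itself (chromosome 1, 94038305 to 94052553), averaged 2.7 ± 1.29, 4.27 ± 0.322 and 3.15 ± 2.11 FPKM.

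**Figure D1:**
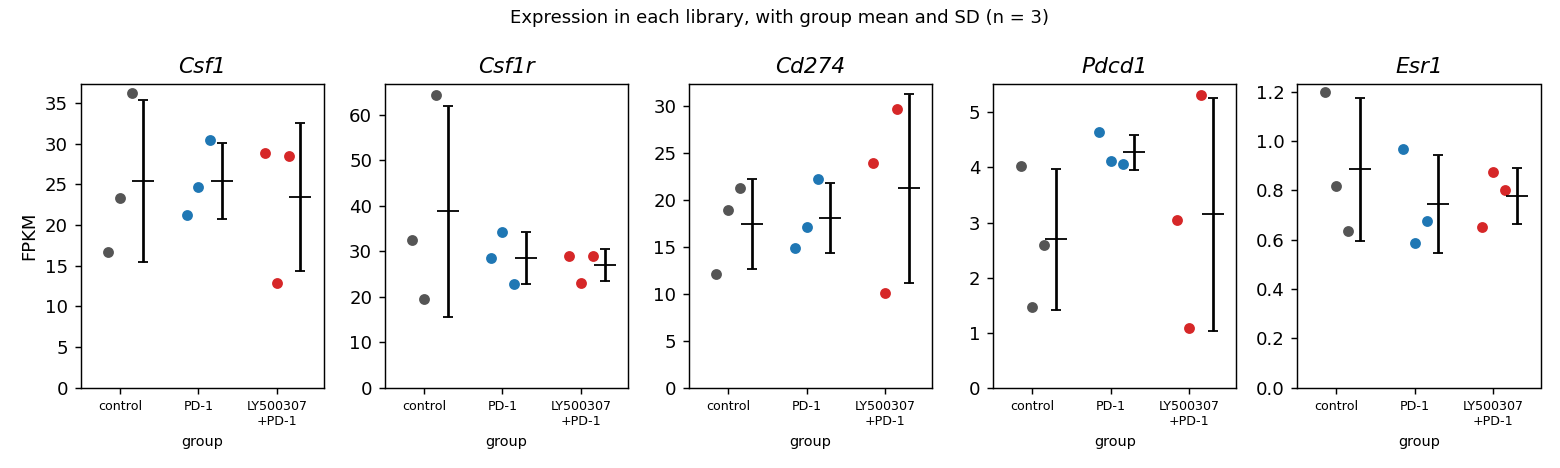
FPKM of Csf1, Csf1r, Cd274, Pdcd1 and Esr1 (vertical axes, each from 0) in the 3 libraries of each group (points), with the group mean and SD (bars). The groups overlap for Csf1, Csf1r, Cd274 and Esr1, and the PD-1 libraries lie above the control libraries for Pdcd1, whose log2 fold change of 0.57 had an adjusted p of 1.

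The first comparison asked what PD-1 treatment alone did. Named genes were taken only from those with a mean of 1 FPKM or more whose groups did not overlap. Among them, the smallest unadjusted p belonged to Sept8, Rps6ka3, Acadsb, Ndufab1-ps and Fpgs on the higher side. On the lower side it belonged to Fip1l1, Phospho1, Paip2, Gper1 and Ttll7. Sept8, a septin (chromosome 11, 53519257 to 53549565), stood at 20.4 ± 1.53 against 6.61 ± 0.836 FPKM, a log2 fold change of 1.49 (SE 0.20). Rps6ka3, a kinase downstream of ERK (chromosome X, 159210307 to 159368244), stood at 6.19 ± 1.37 against 1.38 ± 0.385 FPKM, and Fip1l1, a factor of mRNA polyadenylation, at 3.69 ± 0.35 against 7.58 ± 0.878 FPKM. Log2 fold changes were 1.59 (SE 0.22) for Rps6ka3, 1 (SE 0.18) for Acadsb, an acyl-CoA dehydrogenase, 0.83 (SE 0.15) for the pseudogene Ndufab1-ps and 0.59 (SE 0.12) for Fpgs, the folylpolyglutamate synthase. They were -0.87 (SE 0.12) for Fip1l1, -1.16 (SE 0.18) for Phospho1, a phosphatase of bone mineralization, -0.56 (SE 0.11) for Paip2, -0.96 (SE 0.19) for Gper1, the G protein-coupled estrogen receptor, and -1 (SE 0.21) for Ttll7. Ndufab1-ps may share reads with its parent gene. No gene passed limma's test at a Benjamini-Hochberg adjusted p under 0.05 (0 of 13990), and the smallest adjusted p was 0.231. At an unadjusted p under 0.05 there were 342 genes, 168 higher and 174 lower, where 700 would be expected by chance, and 6.7% of genes had groups that did not overlap, against 10% by chance. Log2 fold changes of 0.05 (SE 0.34) for Csf1 (95% interval -0.73 to 0.83), -0.29 (SE 0.36) for Csf1r (-1.11 to 0.53) and 0.06 (SE 0.36) for Cd274 (-0.76 to 0.89) were within the spread between libraries. Pdcd1 was higher in every PD-1 library than in every control library, with a log2 fold change of 0.57 (SE 0.39) (95% interval -0.30 to 1.44) that did not pass limma's test (adjusted p = 1).

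Among the 23 gene lists tested, interferon response genes and T and NK cell markers passed camera with its preset correlation in PD-1 against control. Of the interferon response genes, 22 of 26 were higher in PD-1, with a median log2 fold change of 0.21 (camera adjusted p = 5.8e-08). The adjusted p was 0.9 with an estimated correlation. The interferon median was 0.15 without control replicate 2 and 0.43 without control replicate 3. Ifit3 stood at 41.2 ± 2.55 against 27.8 ± 7.47 FPKM and Isg15 at 114 ± 4.29 against 87.1 ± 15.6 FPKM, both interferon-induced genes. Of the T and NK cell markers, 17 of 19 were higher, with a median of 0.27 (camera adjusted p = 0.00012, and adjusted p = 0.9 with an estimated correlation). Prf1, which encodes the cytotoxic protein perforin, stood at 13.7 ± 3.09 against 5.81 ± 1.32 FPKM and Cd8b1, a chain of the CD8 coreceptor, at 4.69 ± 0.96 against 2.82 ± 0.947 FPKM. T and NK cell scores are the mean log2(FPKM + 1) deviation of the markers from their means over all libraries. They spanned the equivalent of 1.94-fold in FPKM + 1 between the control libraries themselves. The T and NK cell marker median was 0.17 without control replicate 1, 0.10 without control replicate 2 and 0.57 without control replicate 3. The T and NK cell call was also lost without control replicate 1 (adjusted p = 0.16), within a range of 2.6e-13 to 0.9 over the 12 alternatives tested with camera. None of the members of either list passed over all genes or adjusted over the list alone.

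The remaining lists did not pass in PD-1 against control. Here and below, the member said to lead a list is the one with the smallest unadjusted p. Its direction can be opposite to that of the list. Of the estrogen receptors and targets, 6 of 12 were higher (median log2 fold change 0.02, adjusted p = 0.63), and Gper1 was the 1 member that passed adjusted over the list alone, at 0.446 ± 0.247 against 1.8 ± 0.355 FPKM. Of the myeloid growth factors and chemokines, 15 of 19 were higher (median log2 fold change 0.19, adjusted p = 0.18). The list was led by Il34, which was lower, at 10.6 ± 0.68 against 12.8 ± 1.66 FPKM. The neutrophil markers (median log2 fold change 0.18, adjusted p = 0.13) were led by Retnlg, at 13.6 ± 7.71 against 5.4 ± 1.07 FPKM. The monocyte and macrophage markers (median log2 fold change -0.06, adjusted p = 0.62) were led by Mrc1, at 8.2 ± 1.6 against 12.9 ± 7.87 FPKM. Of the fibroblast and matrix markers, 17 of 19 were lower (median log2 fold change -0.23, adjusted p = 0.059), with Pdgfrb at 6.62 ± 1.35 against 8.82 ± 1.44 FPKM. Of the endothelial markers, 9 of 12 were lower (median log2 fold change -0.12, adjusted p = 0.13), with Cdh5 at 16.6 ± 0.566 against 20.3 ± 3.19 FPKM. The 15 lists that follow had camera adjusted p between 0.059 and 0.93. The mammary epithelial list (median log2 fold change 0.00) was led by Ovol1, with a log2 fold change of 0.34 (SE 0.20). The mesenchymal transition list (median log2 fold change 0.00) was led by Tgfb1, with -0.14 (SE 0.09). Antigen presentation genes (median log2 fold change 0.09) were led by Psmb9, an immunoproteasome subunit, at 41 ± 5.6 against 35.4 ± 0.156 FPKM. Checkpoint genes (median log2 fold change 0.05) were led by Ido1, at 6.53 ± 2.23 against 4.02 ± 1.18 FPKM. Cell cycle genes (median log2 fold change -0.07) were led by Cdc20 with -0.26 (SE 0.37). Hypoxia and glycolysis genes (median log2 fold change 0.11) were led by Gapdh with 0.22 (SE 0.13), and p53 targets (median log2 fold change -0.01) by Trp53inp1 with -0.40 (SE 0.19). The stress list (median log2 fold change 0.02) was led by Sesn2 with -0.27 (SE 0.20). Cholesterol biosynthesis (median log2 fold change 0.08) was led by Fdft1 with -0.31 (SE 0.20), and nuclear oxidative phosphorylation (median log2 fold change 0.05) by Cycs with 0.24 (SE 0.13). Ribosomal protein genes (median log2 fold change 0.04) were led by Rps14 with 0.11 (SE 0.08), and replication-dependent histones (median log2 fold change 0.10) by Hist2h3b with 0.96 (SE 0.43). Skeletal muscle markers (median log2 fold change 0.11) were led by Acta1 with 0.53 (SE 0.67). Immediate early genes (median log2 fold change 0.09) were led by Zfp36 with 0.28 (SE 0.16), and NF-kB targets (median log2 fold change 0.06) by Bcl3 with -0.14 (SE 0.14). Leaving out 1 library turned the direction of the median of 17 of the 21 lists that did not pass in PD-1 against control. The medians then ranged from -0.03 to 0.08 for estrogen receptors and targets, 0.02 to 0.42 for myeloid growth factors, -0.04 to 0.51 for neutrophil markers, -0.37 to 0.31 for monocyte and macrophage markers, -0.41 to 0.06 for fibroblast markers and -0.22 to 0.02 for endothelial markers.

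The second comparison asked what the combination of LY500307 and PD-1 treatment did. Endothelial markers were lower in LY500307+PD-1 than in control for 12 of 12 members tested, with a median log2 fold change of -0.40. Interferon response genes were higher for 25 of 26, with a median of 0.31. Interferon scores were -0.29, -0.38 and 0.12 in the control libraries and 0.13, 0.15 and 0.16 in the LY500307+PD-1 libraries, so control 3 lay close to the treated libraries. Both lists had an adjusted p of 0.28 with an estimated correlation. Among single genes whose groups did not overlap, selected as above, the smallest unadjusted p belonged to F10, Phospho1, Rnu73b, Apc and Ramp2 on the lower side. On the higher side it belonged to Sept8, Fpgs, Stfa3, Apol10b and Adamts14. F10, coagulation factor X (chromosome 8, 13037308 to 13056676), stood at 1.7 ± 0.211 against 4.26 ± 0.515 FPKM, a log2 fold change of -0.96 (SE 0.13). Phospho1 stood at 6.68 ± 1.65 against 17.4 ± 2.77 FPKM, Ramp2, a partner of the adrenomedullin receptor, at 1.7 ± 0.174 against 4.93 ± 1.45 FPKM and the tumour suppressor gene Apc at 0.751 ± 0.221 against 2.67 ± 0.416 FPKM. Stfa3, a stefin that inhibits cysteine proteases, stood at 15.4 ± 10.8 against 1.75 ± 0.487 FPKM, and its libraries held 26.6, 14.5 and 5.18 FPKM in LY500307+PD-1. Log2 fold changes were 1.10 (SE 0.20) for Sept8, 0.62 (SE 0.12) for Fpgs, 2.34 (SE 0.48) for Stfa3, 0.65 (SE 0.14) for Apol10b, 0.89 (SE 0.20) for Adamts14, a procollagen peptidase, and -1.39 (SE 0.22) for the small RNA Rnu73b. No gene passed limma's test at an adjusted p under 0.05 (0 of 13990). The smallest adjusted p was 0.386, and 561 genes had an unadjusted p under 0.05, 249 higher and 312 lower, against 700 expected by chance. Groups did not overlap for 7.9% of genes, against 10% by chance. Csf1 differed by -0.13 (SE 0.34) on the log2 scale (95% interval -0.91 to 0.65), Csf1r by -0.35 (SE 0.36) (-1.17 to 0.47), Cd274 by 0.18 (SE 0.36) (-0.65 to 1.01) and Pdcd1 by 0.09 (SE 0.39) (-0.79 to 0.96), each within the spread between libraries.

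In LY500307+PD-1 against control, 8 lists passed camera with its preset correlation, and 0 passed with an estimated correlation. The endothelial markers (camera adjusted p = 6.3e-10) had an adjusted p of 0.28 with an estimated correlation. Of its 12 members tested, 6 passed adjusted over the list alone and 0 over all genes. Cldn5, a tight junction protein of endothelium, stood at 9.3 ± 2.55 against 21.5 ± 8.73 FPKM and the receptor gene Robo4 at 1.67 ± 0.181 against 3.05 ± 0.728 FPKM. The endothelial median was between -0.53 and -0.32 when any 1 of the 6 libraries was left out. Among hemoglobin transcripts Hba-a2 stood at 11.1 ± 4.69 against 17 ± 6.02 FPKM, and 0 of the 4 erythroid members tested passed adjusted over the list alone. LY500307+PD-1 replicate 2, at 16.3 FPKM of Hba-a2, lay above control 2 and control 3, at 16 and 11.5 FPKM. Gm42418, a gene model within ribosomal RNA that was chosen after its values were seen, stood at 1650 ± 436 against 2370 ± 411 FPKM, and the groups overlapped. Interferon response genes (camera adjusted p = 3e-11, and adjusted p = 0.28 with an estimated correlation) included Ifit3 at 46.5 ± 5.21 against 27.8 ± 7.47 FPKM and Isg15 at 123 ± 11 against 87.1 ± 15.6 FPKM. Antigen presentation genes were higher for 15 of 18, with a median of 0.09 (camera adjusted p = 0.0092, and adjusted p = 0.88 with an estimated correlation). Their median was 0.05 without control replicate 1, 0.01 without control replicate 2, 0.28 without control replicate 3, 0.05 without LY500307+PD-1 replicate 1, 0.18 without LY500307+PD-1 replicate 2 and -0.04 without LY500307+PD-1 replicate 3. Psmb9 stood at 46.9 ± 2.65 against 35.4 ± 0.156 FPKM and Psmb10 at 149 ± 11.5 against 117 ± 8.32 FPKM. T and NK cell markers had a median of 0.18 (camera adjusted p = 0.038, and adjusted p = 0.88 with an estimated correlation), with Foxp3 at 2.1 ± 0.615 against 0.876 ± 1.28 FPKM and Gzmb at 26.8 ± 9.43 against 19.1 ± 11.6 FPKM. The T and NK cell median was 0.06 without control replicate 1, 0.00 without control replicate 2, 0.44 without control replicate 3, 0.09 without LY500307+PD-1 replicate 1, 0.41 without LY500307+PD-1 replicate 2 and 0.00 without LY500307+PD-1 replicate 3. That call was also lost with no filter on low values (adjusted p = 0.19), with only the 6 libraries compared (0.056), without control replicate 1 (0.7), without control replicate 2 (0.52), without LY500307+PD-1 replicate 1 (0.13) and without LY500307+PD-1 replicate 3 (0.93), within a range of 2e-08 to 0.93 over the 12 alternatives tested with camera. The antigen presentation call was also lost without control replicate 1 (adjusted p = 0.062), without control replicate 2 (0.19) and without LY500307+PD-1 replicate 3 (0.26), within a range of 0.00029 to 0.88 over the 12 alternatives tested with camera.

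Lists of growth and metabolism also passed with the preset correlation in LY500307+PD-1 against control. Cholesterol biosynthesis genes were higher for 16 of 18, with a median of 0.41 (camera adjusted p = 4.1e-07, and adjusted p = 0.73 with an estimated correlation). Lss, the lanosterol synthase, stood at 2.46 ± 0.113 against 1.48 ± 0.174 FPKM and Sqle, the squalene epoxidase, at 14.8 ± 2.76 against 10.4 ± 1.4 FPKM. Cell cycle genes were higher for 27 of 27, with a median of 0.35 (camera adjusted p = 2.4e-05, and adjusted p = 0.88 with an estimated correlation), including Rrm2 at 24.4 ± 12.1 against 13.6 ± 3.55 FPKM and Mcm3 at 25.9 ± 6.11 against 18.4 ± 9.48 FPKM. Skeletal muscle markers were higher for 8 of 8, with a median of 0.69 (camera adjusted p = 0.00025, and adjusted p = 0.54 with an estimated correlation), including Acta1 at 31.1 ± 29.9 against 6.53 ± 3.61 FPKM and Myl1 at 1.79 ± 0.984 against 0.756 ± 0.533 FPKM. The cell cycle median was 0.14 without control replicate 3, 0.02 without LY500307+PD-1 replicate 2 and 0.54 without LY500307+PD-1 replicate 3. The skeletal muscle median was 0.26 without LY500307+PD-1 replicate 2 and 1.08 without LY500307+PD-1 replicate 3. LY500307+PD-1 replicate 2 held 65.6 FPKM of Acta1, against 14.6 and 13.2 FPKM in the other LY500307+PD-1 libraries. Nuclear oxidative phosphorylation genes had a median of 0.09 (camera adjusted p = 0.027, and adjusted p = 0.88 with an estimated correlation), with Cycs at 24.1 ± 4.03 against 19.3 ± 1.42 FPKM and Sdhb at 43.4 ± 2.18 against 36.2 ± 3.96 FPKM. The oxidative phosphorylation median was 0.01 without LY500307+PD-1 replicate 2 and 0.20 without LY500307+PD-1 replicate 3. This call was also lost with quantile normalization (adjusted p = 0.092), without control replicate 1 (0.062), without control replicate 2 (0.24), without LY500307+PD-1 replicate 1 (0.06) and without LY500307+PD-1 replicate 2 (0.93), within a range of 4.9e-05 to 0.93 over the 12 alternatives tested with camera. The cell cycle call was also lost without control replicate 3 (adjusted p = 0.26) and without LY500307+PD-1 replicate 2 (0.63), within a range of 1.9e-10 to 0.88 over the 12 alternatives tested with camera. The skeletal muscle call was also lost without LY500307+PD-1 replicate 2 (adjusted p = 0.067), within a range of 2.2e-06 to 0.54 over the 12 alternatives tested with camera.

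**Figure D2:**
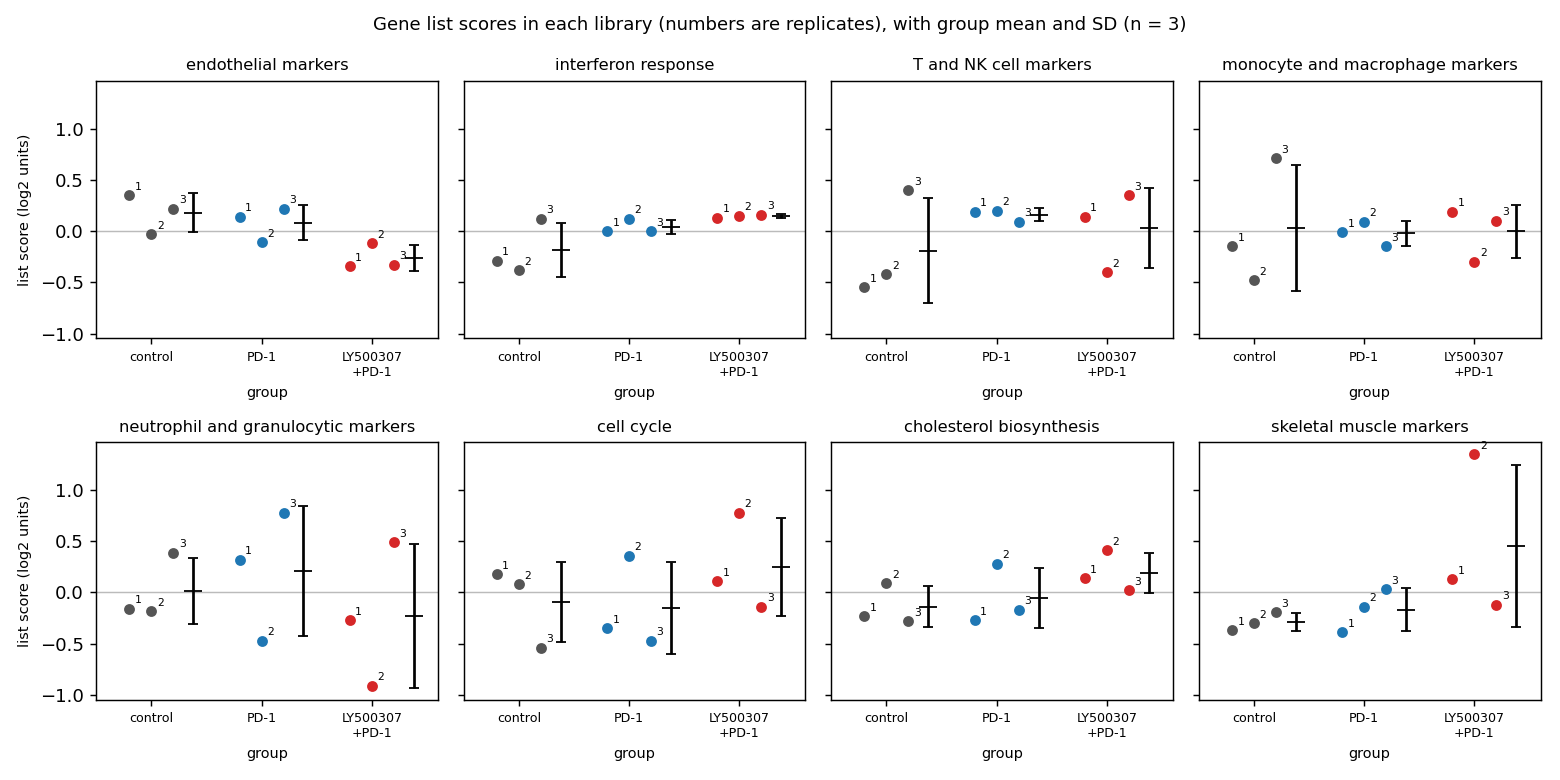
Scores of 8 gene lists (vertical axis, mean over members of the log2 deviation from the mean of 9 libraries) in each library (points, numbered by replicate), with the group mean and SD (bars, n = 3). Endothelial scores of the LY500307+PD-1 libraries are -0.34, -0.12 and -0.33. They are 0.35, -0.03 and 0.22 in control and 0.14, -0.11 and 0.22 in PD-1, so LY500307+PD-1 replicate 2 lies close to PD-1 replicate 2. LY500307+PD-1 replicate 2 has the highest cell cycle and skeletal muscle scores of the 9 libraries.

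The other lists did not pass in LY500307+PD-1 against control. Among estrogen receptors and targets (median log2 fold change -0.07, adjusted p = 0.41), Gper1 stood at 0.553 ± 0.165 against 1.8 ± 0.355 FPKM and was the 1 member that passed adjusted over the list alone. Arg1, which encodes arginase 1, stood at 38.5 ± 4.67 against 72.8 ± 20.9 FPKM among monocyte and macrophage markers (median log2 fold change -0.17, adjusted p = 0.54). Vegfa stood at 18.9 ± 5.02 against 29 ± 4.3 FPKM among myeloid growth factors and chemokines (median log2 fold change -0.09, adjusted p = 0.38). Ngp stood at 0.495 ± 0.626 against 2.16 ± 1.29 FPKM among neutrophil markers (median log2 fold change -0.14, adjusted p = 0.087). Krt5 stood at 25.8 ± 33.9 against 1 ± 1.5 FPKM among mammary epithelial markers (median log2 fold change 0.03, adjusted p = 0.31). The 10 lists that follow had camera adjusted p between 0.12 and 0.97 in this comparison. Ido1 led the checkpoint genes (median log2 fold change -0.01) with a log2 fold change of 0.83 (SE 0.33), and Pdgfrb the fibroblast markers (median log2 fold change -0.02) with -0.24 (SE 0.19). Fn1 led the mesenchymal transition genes (median log2 fold change -0.02) with -0.29 (SE 0.20). Egln3 led the hypoxia and glycolysis genes (median log2 fold change 0.11) with -0.61 (SE 0.28) and Aen the p53 targets (median log2 fold change 0.01) with 0.63 (SE 0.30). Chac1 led the stress genes (median log2 fold change 0.12) with 0.73 (SE 0.24). Rps16 led the ribosomal protein genes (median log2 fold change 0.05) with 0.14 (SE 0.12) and Hist1h4a the histones (median log2 fold change 0.13) with -0.77 (SE 0.30). Ier3 led the immediate early genes (median log2 fold change -0.10) with -0.32 (SE 0.21), and Nfkbie the NF-kB targets (median log2 fold change 0.06) with 0.26 (SE 0.18). Leaving out 1 library turned the direction of the median of 13 of the 15 lists that did not pass in LY500307+PD-1 against control. The medians then ranged from -0.18 to 0.00 for estrogen receptors and targets, -0.54 to 0.25 for monocyte and macrophage markers, -0.31 to 0.17 for myeloid growth factors, -0.56 to 0.10 for neutrophil markers, -0.08 to 0.19 for mammary epithelial markers and -0.32 to 0.17 for fibroblast markers.

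The third comparison set LY500307+PD-1 against PD-1 and asked what LY500307 added. Endothelial markers were lower for 11 of 12 members tested and neutrophil markers for 13 of 15, with medians of -0.37 and -0.42, and cell cycle genes were higher for 26 of 27, with a median of 0.40. Each of these lists had an adjusted p of 0.84 with an estimated correlation, and without LY500307+PD-1 replicate 2 the cell cycle median was 0.13. Neutrophil scores were 0.32, -0.47 and 0.78 in the PD-1 libraries and -0.27, -0.91 and 0.49 in the LY500307+PD-1 libraries, so the groups overlapped. Endothelial scores of PD-1 replicate 2 and LY500307+PD-1 replicate 2 lay close together, at -0.11 and -0.12. Among single genes whose groups did not overlap, selected as above, the smallest unadjusted p on the higher side belonged to Fip1l1, Ino80b, Mbd6, Stfa3 and Arhgap27os1. On the lower side it belonged to Rps6ka3, Apc, Dnajb4, Rnu73b and Hba-a2. Fip1l1 stood at 7.11 ± 0.411 against 3.69 ± 0.35 FPKM and Rps6ka3 at 1.81 ± 0.702 against 6.19 ± 1.37 FPKM. Ino80b, a subunit of the INO80 chromatin remodeller, stood at 21.7 ± 0.436 against 11.5 ± 1.44 FPKM, and Stfa3 at 15.4 ± 10.8 against 1.75 ± 0.858 FPKM. Log2 fold changes were 0.79 (SE 0.12) for Fip1l1, 0.87 (SE 0.15) for Ino80b, 0.56 (SE 0.11) for Mbd6, 2.37 (SE 0.48) for Stfa3 and 0.67 (SE 0.15) for the antisense gene Arhgap27os1. They were -1.37 (SE 0.22) for Rps6ka3, -1.03 (SE 0.20) for Apc, -0.90 (SE 0.18) for the chaperone gene Dnajb4, -1.11 (SE 0.22) for Rnu73b and -1.48 (SE 0.31) for Hba-a2. Whether counting used strand is not given in the sources used here, so Arhgap27os1 cannot be separated from its antisense partner. No gene passed limma's test at an adjusted p under 0.05 (0 of 13990), the smallest adjusted p was 0.911, and 398 genes had an unadjusted p under 0.05, 166 higher and 232 lower, against 700 expected by chance. Groups did not overlap for 7.6% of genes, against 10% by chance. Csf1 differed by -0.18 (SE 0.34) on the log2 scale (95% interval -0.96 to 0.60), Csf1r by -0.06 (SE 0.36) (-0.88 to 0.76), Cd274 by 0.12 (SE 0.36) (-0.71 to 0.94) and Pdcd1 by -0.48 (SE 0.39) (-1.36 to 0.39), again within the spread between libraries.

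In LY500307+PD-1 against PD-1, 6 lists passed camera with its preset correlation and 0 passed with an estimated correlation, where the adjusted p of each of these lists was 0.84. Among endothelial markers (camera adjusted p = 9.8e-07), Pecam1 stood at 7.83 ± 0.609 against 11.1 ± 2.39 FPKM and Tie1 at 3.19 ± 0.938 against 4.74 ± 0.457 FPKM. Hemoglobin genes averaged lower in the same group, and all 4 erythroid members tested passed adjusted over the list alone and 0 over all genes, with a median log2 fold change of -1.36 and Hba-a2 at 11.1 ± 4.69 against 31.4 ± 5.15 FPKM. Hemoglobin genes have near-identical copies, so the split between them is uncertain. Gm42418 stood at 1650 ± 436 against 2590 ± 709 FPKM and AY036118, annotated within it on the opposite strand and also chosen after its values were seen, at 1700 ± 479 against 2600 ± 583 FPKM. Every LY500307+PD-1 library lay below every PD-1 library for both genes, and neither gene passed limma's test (adjusted p = 1). Neutrophil markers (camera adjusted p = 0.00023) included Ngp at 0.495 ± 0.626 against 1.82 ± 0.702 FPKM and Trem1 at 1.29 ± 0.31 against 2.09 ± 0.543 FPKM. The neutrophil median was -0.64 without PD-1 replicate 2. Myeloid growth factors and chemokines were lower for 17 of 19, with a median of -0.28 (camera adjusted p = 0.015), and Il1a stood at 3.44 ± 0.834 against 10.5 ± 8.87 FPKM and Vegfa at 18.9 ± 5.02 against 25 ± 6.46 FPKM. The myeloid factor median was -0.45 without PD-1 replicate 2, -0.16 without PD-1 replicate 3, -0.05 without LY500307+PD-1 replicate 2 and -0.50 without LY500307+PD-1 replicate 3. Cell cycle genes (camera adjusted p = 5.3e-07) included Cdc20 at 41.5 ± 20.2 against 24.6 ± 8.67 FPKM and Ccnb2 at 40.4 ± 17.8 against 25.8 ± 12.2 FPKM. Cholesterol biosynthesis genes were higher for 15 of 18, with a median of 0.28 (camera adjusted p = 6.2e-05), with Hmgcs1 at 21.4 ± 5.33 against 14.9 ± 2.73 FPKM and Lss at 2.46 ± 0.113 against 1.86 ± 0.472 FPKM. Skeletal muscle markers were higher for 8 of 8, with a median of 0.61 (camera adjusted p = 0.0014), with Mylpf at 5.39 ± 4.51 against 1.99 ± 0.452 FPKM and Acta1 at 31.1 ± 29.9 against 9.72 ± 5.36 FPKM. The cell cycle median was 0.61 without PD-1 replicate 2, 0.25 without PD-1 replicate 3, 0.13 without LY500307+PD-1 replicate 2 and 0.62 without LY500307+PD-1 replicate 3. The cholesterol median was 0.17 without PD-1 replicate 1 and 0.15 without LY500307+PD-1 replicate 2. The skeletal muscle median was 0.15 without LY500307+PD-1 replicate 2 and 1.01 without LY500307+PD-1 replicate 3. Over the list alone, 0 members of these 6 lists passed. The myeloid factor call was also lost with no filter on low values (adjusted p = 0.059), without PD-1 replicate 1 (0.082), without PD-1 replicate 3 (0.27), without LY500307+PD-1 replicate 1 (0.06) and without LY500307+PD-1 replicate 2 (0.35), within a range of 8.4e-05 to 0.84 over the 12 alternatives tested with camera. The neutrophil call was also lost without PD-1 replicate 3 (adjusted p = 0.13) and without LY500307+PD-1 replicate 2 (0.11), within a range of 2.1e-08 to 0.84 over the 12 alternatives tested with camera. The cholesterol call was also lost without PD-1 replicate 1 (adjusted p = 0.054) and without LY500307+PD-1 replicate 2 (0.11), within a range of 3.7e-09 to 0.84 over the 12 alternatives tested with camera. The cell cycle call was also lost without LY500307+PD-1 replicate 2 (adjusted p = 0.21), within a range of 4.2e-14 to 0.84 over the 12 alternatives tested with camera. The skeletal muscle call was also lost without LY500307+PD-1 replicate 2 (adjusted p = 0.21), within a range of 3.2e-05 to 0.84 over the 12 alternatives tested with camera.

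Lists that did not pass in LY500307+PD-1 against PD-1 included monocyte and macrophage markers (median log2 fold change -0.06, adjusted p = 0.89), where Arg1 stood at 38.5 ± 4.67 against 73.3 ± 29 FPKM. T and NK cell markers (median log2 fold change -0.08, adjusted p = 0.2) were led by Prf1, at 7.52 ± 3.74 against 13.7 ± 3.09 FPKM. Estrogen receptors and targets (median log2 fold change -0.04, adjusted p = 0.82) were led by Ctsd, at 283 ± 68.7 against 322 ± 53.9 FPKM. Mammary epithelial markers (median log2 fold change 0.07, adjusted p = 0.48) were led by Krt5, at 25.8 ± 33.9 against 0.43 ± 0.257 FPKM, of which LY500307+PD-1 replicate 2 held 64.4 FPKM. The 13 lists that follow had camera adjusted p between 0.07 and 0.87 in this comparison. Fibroblast markers (median log2 fold change 0.13) were led by Dcn with a log2 fold change of 0.62 (SE 0.44). Mesenchymal transition genes (median log2 fold change 0.01) were led by Twist1 with -0.25 (SE 0.13) and interferon response genes (median log2 fold change 0.09) by Irf1 with 0.44 (SE 0.26). Antigen presentation genes (median log2 fold change 0.00) were led by Tap1 with 0.40 (SE 0.18). Checkpoint genes (median log2 fold change -0.02) were led by Nt5e with -0.29 (SE 0.19) and hypoxia and glycolysis genes (median log2 fold change 0.00) by Pfkfb3 with -0.79 (SE 0.53). The p53 targets (median log2 fold change -0.01) were led by Bbc3 with 0.30 (SE 0.17). Stress genes (median log2 fold change 0.15) were led by Chac1 with 0.52 (SE 0.24) and nuclear oxidative phosphorylation genes (median log2 fold change 0.06) by Atp5j with -0.47 (SE 0.16). Ribosomal protein genes (median log2 fold change 0.00) were led by Rps9 with -0.14 (SE 0.10) and histones (median log2 fold change -0.01) by Hist1h4d with -0.70 (SE 0.20). Immediate early genes (median log2 fold change -0.19) were led by Ier3 with -0.35 (SE 0.21) and NF-kB targets (median log2 fold change 0.05) by Tnfaip3 with -0.50 (SE 0.32). Leaving out 1 library turned the direction of the median of 14 of the 17 lists that did not pass in LY500307+PD-1 against PD-1. The medians then ranged from -0.21 to 0.17 for monocyte and macrophage markers, -0.27 to 0.12 for T and NK cell markers, -0.06 to 0.03 for estrogen receptors and targets, -0.13 to 0.31 for mammary epithelial markers and -0.07 to 0.44 for fibroblast markers.

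In 5 lists there were too few members above the filter for a list test. Of the B and plasma cell markers, 2 were tested, and Ighm stood at 5.38 ± 2.9 against 6.12 ± 5.52 FPKM in LY500307+PD-1 and control, while Igkc stood at 2.81 ± 0.671 against 6.39 ± 5.12 FPKM in PD-1 and control. Of the dendritic cell markers, 4 were tested, with median log2 fold changes of -0.09, 0.07 and 0.16 in the order of the comparisons above. Among them Irf8 stood at 14.5 ± 2.58 against 15.7 ± 3.3 FPKM in PD-1 and control, and Ccr7 at 2.53 ± 0.632 against 1.42 ± 0.639 FPKM in LY500307+PD-1 and PD-1. Of the adipocyte markers, Fabp4 alone was tested, with log2 fold changes of 0.18 (SE 0.64), -0.04 (SE 0.64) and -0.22 (SE 0.64). Of the erythroid markers, 4 were tested, with medians of 0.76, -0.65 and -1.36, and 2 of them passed adjusted over the list alone in PD-1 against control, where Hba-a2 stood at 31.4 ± 5.15 against 17 ± 6.02 FPKM. All 13 mitochondrially encoded genes of the list were listed at 0 in every library.

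Both treatments were compared with the same 3 control libraries. No gene was called in both comparisons. At an unadjusted p under 0.05, 116 genes passed both in the same direction, against a mean of 168, a median of 8 and a range of 0 to 3230 in 100 simulations of unchanged groups. Of these simulations, 27 gave as many genes. Independent lists would share 3 higher and 3.9 lower genes. Log2 fold changes of the 2 comparisons correlated across genes, which are not independent, with r = 0.48, against a simulated mean of 0.43 (-0.76 to 0.96). Their covariance was 0.0271, against 0.0366 (-0.0333 to 0.1656). The direction was the same for 67.1% of genes, against 65.5% (21.2% to 91.3%). Each value lay inside a wide simulated range, so the agreement may come from the shared controls, which are too few to divide.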

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

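No gene was called in any of the 3 comparisons (limma, 0 each) under quantile normalization, no filter on low values or a pseudocount of 0.1. The 6 libraries compared alone and the replicate block gave 0 calls as well. A fold minimum of 2 can only remove calls of the main fit, so its 0 was fixed in advance. Leaving out each library gave between 0 and 1 genes for PD-1 against control and between 0 and 2 for each of the other comparisons. Without control replicate 1, Emp1 was called in both comparisons with control, so the overlap of calls was not 0 there. Its log2 fold changes were 2.82 for PD-1 (limma adjusted p = 0.04) and 2.87 for LY500307+PD-1 (limma adjusted p = 0.035). DESeq2, planned as a second test and for the overlap of calls, was not run, since the values are not counts. With the replicate number as a block, 402, 701 and 533 genes had an unadjusted p under 0.05 in the order of the report. Since the block called 0 genes, the overlap of calls could only be 0. Deviations of same-numbered libraries correlated between -0.12 and 0.27, and those of differently numbered libraries of 2 groups between -0.36 and 0.26. These ranges overlap and do not settle whether the numbers mark a shared batch.

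List counts moved more. From 2, 8 and 6 lists, an estimated correlation or fry left 0 in each comparison, since both allow for genes that vary together, and fry does not compare a list with other genes. For PD-1 against control the 6 libraries alone gave 4 lists and the block 5, and the cause was not tested. Leaving out each library gave between 3 and 11 lists for PD-1 against control, between 6 and 11 for LY500307+PD-1 against control and between 3 and 11 for LY500307+PD-1 against PD-1.

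Uncalled genes that turned direction when a library was left out had these ranges of log2 fold change. In PD-1 against control they were -0.20 to 0.33 for Csf1, -0.16 to 0.22 for Cd274, -0.10 to 0.64 for Fabp4, -0.23 to 0.05 for Irf8 and -0.69 to 0.15 for Csf1r. In LY500307+PD-1 against control they were 0.00 to 1.02 for Gzmb (-0.0035 without control replicate 1), -0.75 to 0.42 for Fabp4, -0.11 to 0.62 for Cd274, -0.58 to 0.65 for Ighm, -0.29 to 0.51 for Pdcd1, -0.39 to 0.23 for Csf1 and -0.75 to 0.09 for Csf1r. In LY500307+PD-1 against PD-1 they were -0.18 to 0.56 for Cd274, -0.21 to 0.08 for Csf1r, -0.93 to 0.16 for Fabp4, -0.34 to 0.02 for Ctsd and -0.37 to 0.18 for Csf1. Csf1 in both comparisons of LY500307+PD-1 was above 0 without LY500307+PD-1 replicate 2. That library held 12.9 FPKM of Csf1, the lowest value of the 9 libraries, against 28.8 and 28.5 FPKM in LY500307+PD-1 replicates 1 and 3. Each of these fits differs from the main fit only in the library left out.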

Other observations

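Of the tests of explanations below, the comparison of pseudogenes with mitochondrial transcripts was set out before its result was seen, and the others were chosen after the results were seen.

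The libraries held transcripts of many cell types besides mammary carcinoma, and these genes were chosen after their values were seen. LY500307+PD-1 replicate 2 held 49.1 FPKM of Lor and 43.9 FPKM of Krt10, genes of the outer epidermis, where the other libraries held at most 1.43 and 4.94 FPKM. It had the highest value of all 9 libraries for 10 of 10 adipocyte markers, with 29.6 FPKM of Cfd and 2.91 FPKM of Adipoq, and for 13 of 15 skeletal muscle markers. Lcn2, at 6.22 FPKM, and Cp, at 4.67 FPKM, were lower there than in any other library. Control 1 held 0.302 FPKM of the mast cell protease gene Mcpt4, 1.54 of Tpsab1 and 2.09 of Tpsb2, where control 3 held 64.1, 131 and 144. Control 1 also held 75.5 FPKM of Ibsp, which encodes bone sialoprotein, and 49.7 FPKM of the imprinted RNA H19, against at most 26.5 and 15.4 FPKM elsewhere. Over the 9 libraries, scores of neutrophil markers and of myeloid growth factors and chemokines correlated with r = 0.94 (exact permutation p = 0.00034, adjusted p = 0.0021 over 6 relations) and rho = 0.88 (exact permutation p = 0.0031, adjusted p = 0.018). Without PD-1 3 and LY500307+PD-1 2, r was 0.88. Scores of monocyte and macrophage markers and of cell cycle genes had r = -0.49 (exact permutation p = 0.18, adjusted p = 0.27 over 6 relations) and rho = -0.33 (p = 0.39 by exact permutation, adjusted p = 0.58), and r was -0.29 without control 2 and control 3.

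Host cell markers differed between libraries of the same group. The T and NK cell scores spanned the equivalent of 1.94-fold in FPKM + 1 within control, 1.08-fold within PD-1 and 1.68-fold within LY500307+PD-1. These ratios understate the spread in FPKM, since many of these markers are low. The median FPKM of the tested markers was 0.994, 1.22 and 3.7 in control replicates 1, 2 and 3. The values are scaled to library size, so the depth ratio of 1.056 cannot be set against these ratios. The implied depths point both ways on a difference in depth as the source of these scores, and do not settle it. PD-1 1 and PD-1 2 had the lowest and highest depths, 8240000 and 8700000 fragments, at scores of 0.19 and 0.20. The control libraries, with the widest span of scores, lay between 8380000 and 8510000 fragments. Among them the scores of -0.55, -0.42 and 0.40 rose in the order of depth. Scores of T and NK cell markers and of monocyte and macrophage markers, lists with 0 genes in common, correlated with r = 0.77 (exact permutation p = 0.008, adjusted p = 0.024 over 6 relations) and rho = 0.8 (p = 0.014 by exact permutation, adjusted p = 0.041), r was 0.76 without control 1 and control 2, and it was 0.88 after group means were removed, which is consistent with differing shares of host cells, as tumour tissue might hold. T and NK cell and mammary epithelial scores, which such shares would move apart, had r = -0.33 (exact permutation p = 0.44, adjusted p = 0.53) and rho = -0.02 (p = 0.98 by exact permutation, adjusted p = 0.98), with r = -0.79 without control 1 and control 2, and do not settle it. An effect of treatment common to a group cannot account for differences within that group, and uneven responses to treatment were not tested. Whether treatment adds to the differences between groups stays open. The grouping held 22.8% of the variance of 6 host cell scores, against a mean of 25.0% over 280 groupings (exact permutation p = 0.53).

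Endothelial markers were lower in LY500307+PD-1 than in the other 6 libraries by 0.39 on the log2 scale, a difference that 2 of the 84 splits reach (exact permutation p = 0.024). LY500307+PD-1 replicate 2, with a score of -0.12, lay close to PD-1 replicate 2, at -0.11. Skeletal muscle markers were higher by 0.68, which 2 of the 84 splits reach as well. That muscle difference rests largely on LY500307+PD-1 replicate 2, with a score of 1.35, against 0.13 and -0.12 in replicates 1 and 3. Over the 23 lists the adjusted p of this permutation test was 0.27 for either list, so chance in 1 of many lists remains a candidate explanation. Less stroma of every kind has no support in fibroblast scores, which differed by 0.08 (p = 0.79 by exact permutation) and had r = -0.11 (exact permutation p = 0.77, adjusted p = 0.77 over 6 relations) and rho = 0.03 (p = 0.95 by exact permutation, adjusted p = 0.98) with endothelial scores, r = -0.3 without control 1 and LY500307+PD-1 1, but their spread between libraries leaves it open. A lower blood and vessel content may also contribute, since erythroid and endothelial scores had r = 0.72 (exact permutation p = 0.029, adjusted p = 0.057 over 6 relations) and rho = 0.58 (p = 0.11 by exact permutation, adjusted p = 0.22), and r was 0.62 without PD-1 1 and LY500307+PD-1 3. An effect of LY500307 on endothelial cells stays open and untested.

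All 37 mitochondrially encoded rows were at 0 in every library, and 7 unprocessed pseudogenes averaged 100 FPKM or more. The 4 most abundant, Gm10925, Gm28661, Gm28437 and Gm29216, averaged 3628, 3207, 2824 and 2460 FPKM and lie next to each other on chromosome 1 between 24613189 and 24616197 of GRCm38. Each of the 7 was at least 99.7% identical to a mitochondrial transcript over its alignment (Gm10925 matched mt-Atp6 over 678 nt with 0 mismatches), and together they summed to between 12048 and 14891 FPKM per library. Reads of mitochondrial transcripts may thus have been counted on nuclear copies for the best matches, mt-Atp6, mt-Co1, mt-Co2, mt-Co3, mt-Nd3, mt-Nd4 and mt-Nd4l. For mt-Co1 (mitochondrial positions 5328 to 6872) and mt-Nd4 (10167 to 11544) the alignments spanned only 483 and 876 nt. These copies do not account for reads from the rest of either gene, and so not for a value of 0. Other rows at 0, such as mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6 and mt-Cytb, were the best match of none of the 7 and are not accounted for. No biological explanation was tested.

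Other splits of the 6 libraries of each comparison were fitted in the same way. The 3 comparisons each allow 10 splits, which is too few for a share under 0.05, and the real split called 0 genes in each. The highest other split called 3 genes for PD-1 against control, 8 for LY500307+PD-1 against control and 1 for LY500307+PD-1 against PD-1. The split with 8 set control 1, control 2 and LY500307+PD-1 2 apart from the other 3 libraries and had 1762 genes at an unadjusted p under 0.05, against 561 for the real split. In PD-1 against control the mean log2 fold change of interferon response genes had a size of 0.224, and 3 of the 9 other splits gave as much, up to 0.304. In LY500307+PD-1 against control that size was 0.329, against at most 0.323 in the other splits, and the endothelial size was 0.442, against at most 0.38. In LY500307+PD-1 against PD-1 the endothelial size was 0.342, against at most 0.337.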
